A study of Mus musculus with 10 samples.

How the data were processed

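RNA from the motor cortex of 10 mice, 5 WT and 5 KO, was extracted with a kit from Kurabo and made into libraries with NEBNext Ultra, per the labels' protocols. The submitters' processing notes name mm10 and DESeq2, with no role for either; the aligner, the counting tool and the annotation release are not given in the sources used here. The deposited table gives FPKM per gene and library, with gene identifiers, coordinates and gene length, per the file headers. The product of FPKM and gene length gave whole fragments in 100% of the values above 0, within 0.02 of a whole number, after division by 1 step per library. The authors' FPKM are thus relative to the fragments assigned to the genes of the table. The kit is not stated to mark strand, so reads of overlapping sense and antisense genes cannot be told apart. Of 35275 gene identifiers 34490 matched GENCODE release M21, and 99.9% of those lay at overlapping coordinates.

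Groups and replicate numbers were taken from the sample titles. The total per library ranged from 22793058 to 28827871 fragments, and no pair among the 45 pairs of libraries agreed within sampling noise (lowest chi-square per gene 7.22, where sampling alone gives about 1). The spread between mice, not the depth, sets the precision of most values. Floors for a gene with 0 fragments use 3 fragments over the group and cover counting error only.

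KO was compared with WT in limma 3.58.1 under R 4.3.3, by lmFit and eBayes with a trend on log2(FPKM + 1), over the genes with a mean of at least 0.5 FPKM, with genotype alone in the model. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. Camera sets a list against all other genes, so a list called higher or lower is so relative to them. The median log2 fold change of all tested genes was 0.0779. Tests of single values were exact permutation tests over 252 assignments, of which the smallest p is 0.00794. The tests, the lists and the following rule were fixed before the data were examined. The text names Tmem259; Slc1a2, Slc1a3, Glul, Gfap, Tnf and Tnfrsf1a; the 8 called genes in each direction with the largest fold change and groups that do not overlap, without predicted genes, pseudogenes and sex-linked genes; and up to 3 members of each list with the lowest p. Genes named outside it, H2-K1, Omp and those of the closing section, were chosen after their values were seen. 1 gene that the rule names is not reported here.

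Alternatives covered the pseudocount, the filter, scaling, the variance model, library weights, a block, a Y-linked covariate, each library left out, an exact test per gene, other thresholds and other list tests. Fits on recovered fragments with limma voom, a covariate of olfactory bulb markers, a correction for gene length and all fits without the library labelled KO3 and a further library were chosen after seeing the data.

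The limma step was tested on simulated counts for the comparison of KO and WT, drawn from the WT means and real library sizes with a dispersion of 0.00575, with 200 genes changed. Among 14312 genes tested it called 92.3% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 unchanged genes called, and 0 genes were called where nothing was changed. The simulated genes were independent, had the same dispersion and included no library apart from its group. These rates therefore check the step itself and do not carry over to the real libraries.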

Results

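RNA was sequenced from the motor cortex of C57BL/6 mice at postnatal day 22, in 5 wild-type (WT) mice and 5 mice in which membralin, encoded by Tmem259, was deleted in astrocytes (KO). Membralin is a membrane protein of the endoplasmic reticulum. The deposited values correspond to between 22793058 and 28827871 fragments per WT library and between 22968013 and 27567361 per KO library. Each group held 2 libraries with Y-linked transcripts and 3 without. The comparison asks which transcripts differ in the cortex when astrocytes lack membralin, with attention to the handling of glutamate.

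Tmem259 (ENSMUSG00000013858, chromosome 10, 79974948 to 79984330, minus strand, mm10) measured 25.5, 23.8, 25.0, 32.4 and 30.4 FPKM in WT1 to WT5. It measured 20.1, 18.5, 16.9 and 26.2 FPKM in KO1, KO2, KO4 and KO5, and 34.4 FPKM in the library labelled KO3, the highest of the 10. The group means were 27.4 ± 3.73 FPKM (SD, n = 5) in WT and 23.2 ± 7.16 FPKM (SD, n = 5) in KO. The difference did not pass the test (log2 fold change -0.27, SE 0.16, limma adjusted p = 0.275; exact two-sided permutation p = 0.214). Without the library labelled KO3 the KO mean was 20.4 ± 4.05 FPKM (SD, n = 4) and the log2 fold change was -0.42 (limma adjusted p = 0.0278; exact permutation p = 0.0556). Leaving out the highest KO value of a gene lowers its KO mean, so this fit is no independent test of a fall. The values cover the whole tissue, in which other cells keep the gene, and the gene overlaps Grin3b on the opposite strand. Because the targeted gene goes against the label of that library, every direction given for KO includes the library labelled KO3 unless it is said to be left out.

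In KO cortex 9 of 11 pan-reactive astrocyte genes, 18 of 19 complement and MHC genes and 17 of 22 interferon response genes rose. Each of these lists was called higher by camera, and each had adjusted p = 0.318 with an estimated correlation. Gfap, the intermediate filament of astrocytes, averaged 97.9 ± 14.8 FPKM (SD, n = 5) in WT and 427 ± 204 FPKM (SD, n = 5) in KO, a 4.36-fold difference of means. It was 106 FPKM in the library labelled KO3, within the WT range, and 507 ± 112 FPKM (SD, n = 4) in the other KO libraries. Complement C4b rose from 3.68 ± 0.67 to 22.3 ± 10.3 FPKM (SD, n = 5 each), and every KO library lay above every WT library, as the rule that named it requires. It was 5.22 FPKM in the library labelled KO3, close to the highest WT value of 4.37 FPKM, and 26.5 ± 4.65 FPKM (SD, n = 4) in the other KO libraries. Rims1 and Shank1, which encode synaptic scaffolds, fell.

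Of 14497 genes tested, 1926 passed in limma, 1417 higher and 509 lower in KO, and 4758 had an unadjusted p under 0.05 where 725 were expected by chance. With median-of-ratios scaling the split was 625 higher and 901 lower. Among the called genes, 54 rose and 6 fell by at least 1 on the log2(FPKM + 1) scale. The count fell to 2 genes without WT1, without KO2 or without KO4, although 3934, 4114 and 3742 genes had an unadjusted p under 0.05 in those fits. The count was 3763 without the library labelled KO3. It was 1186 without WT2, 1229 without WT3, 1263 without WT4, 847 without WT5, 576 without KO1 and 987 without KO5. With a score of olfactory bulb markers as a covariate it was 0, and 2141 when the library labelled KO3 was also left out. In the 2 WT and 4 KO libraries with Omp, an olfactory bulb marker, of at least 1 FPKM it was 0. With the library labelled KO3 left out, leaving out any further library gave between 2415 and 3423 genes. Of the 1926 genes, 1919 also passed in the same direction without it.

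**Figure D1:**
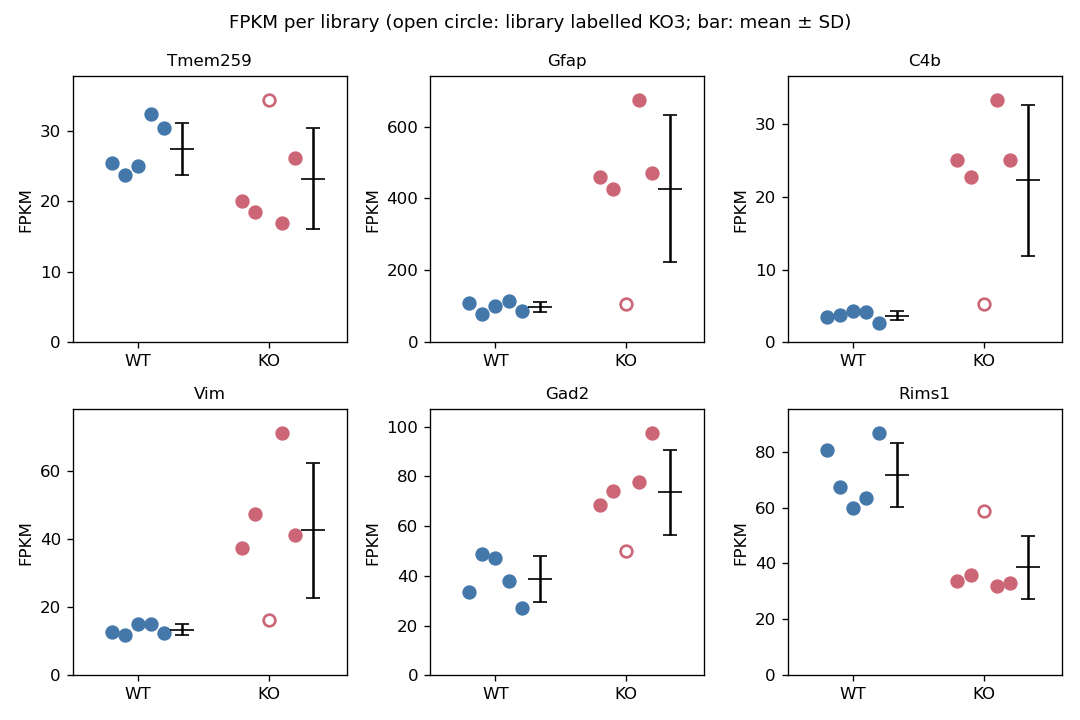
FPKM of 6 genes in each WT (blue) and KO (red) library, with the mean and SD of each group in black and the library labelled KO3 as an open circle. Gfap in that library was 106 FPKM, against 426 to 673 FPKM in the other KO libraries, and Tmem259 in it was the highest of the 10.

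The genes with the largest rise among those whose groups did not overlap, without predicted genes, pseudogenes and sex-linked genes, were C4b, Bst2, Lyz2, Vim, Ifitm3, Ppm1j, Oasl2 and Cd74. Called genes outside these limits rose further than C4b. Gfap, whose groups overlapped, rose by 1.91 on the log2 scale. Bst2, an interferon-induced membrane protein, rose by 1.52 on the log2 scale (SE 0.23, limma adjusted p = 0.018). Lyz2, a lysozyme of myeloid cells, rose by 1.47 (SE 0.24), and Vim, an intermediate filament of reactive astrocytes, by 1.46 (SE 0.28). Cd74, the invariant chain of class II antigen presentation, rose from 1.88 ± 0.55 to 6.52 ± 2.27 FPKM (SD, n = 5 each). Reads of C4b and Lyz2 can be shared with the close paralogs C4a and Lyz1, so their levels are uncertain to that extent. Among called genes whose groups did not overlap, with the same kinds of genes left out, those with the largest fall were Aldh1a1, Rims1, Kcnk4, Cpne9, Kcnh5, Kcnj9, Dgkz and Shank1. Called genes outside these limits fell further. Rims1, a scaffold of the presynaptic active zone, went from 71.6 ± 11.5 to 38.6 ± 11.3 FPKM (SD, n = 5 each), and Shank1, a postsynaptic scaffold, from 229 ± 35.3 to 140 ± 29.5 FPKM. Kcnk4, Kcnh5 and Kcnj9 encode potassium channels, and their log2 fold changes were -0.85, -0.79 and -0.74. Of all tested genes 7.55% had groups that did not overlap, where chance gives 0.79%.

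The main astrocyte genes of glutamate uptake did not pass the test. Slc1a3, an astrocyte glutamate transporter, measured 137 ± 6.56 FPKM in WT and 136 ± 5.95 FPKM in KO (SD, n = 5 each; limma adjusted p = 0.972). Slc1a2, the main glutamate transporter of forebrain astrocytes (chromosome 2, 102658659 to 102790784), measured 441 ± 35.7 and 383 ± 44.4 FPKM (log2 fold change -0.20, limma adjusted p = 0.132, unadjusted p = 0.0392). In 4 of the 5 KO libraries Slc1a2 lay below every WT library. Without the library labelled KO3 its log2 fold change was -0.23 (limma adjusted p = 0.0943). Glul, glutamine synthetase, measured 748 ± 97.5 and 640 ± 104 FPKM (log2 fold change -0.23, adjusted p = 0.198), and without the library labelled KO3 its log2 fold change was -0.32 (adjusted p = 0.0338). Of 17 measured genes of glutamate uptake and metabolism 4 rose, among them Bcat1, Slc1a4 and Slc7a11, the cystine and glutamate exchanger, and none fell; 5 rose adjusted over the list alone. That list was not called by camera (adjusted p = 0.265). Its mean was higher in KO by 0.13 on the log2 scale (exact permutation p = 0.0159, 0.0529 after adjustment over the lists).

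Tnfrsf1a, a receptor of tumour necrosis factor, rose from 4.50 ± 0.39 to 7.78 ± 1.63 FPKM (SD, n = 5 each; limma adjusted p = 0.0186). Tnf itself was below the filter. It had 0 fragments in the 5 WT libraries, where 3 fragments over the group would be 0.0140 FPKM, and 7 fragments in 4 of the 5 KO libraries, including the library labelled KO3. Pooled over the KO libraries its level was 0.0343 FPKM, 2.45-fold that floor, a ratio that leaves out the counting error of the 7 fragments. No library held more than 3 fragments (exact permutation p = 0.0476 for KO against WT). Of 19 measured genes of tumour necrosis factor and NF-kB signalling 7 rose, including Nfkb2 and Icam1, and none fell; 11 rose adjusted over the list alone. That list was called higher by camera (adjusted p = 0.00195), but not with an estimated correlation (adjusted p = 0.318).

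With a preset correlation 16 of 30 gene lists were called, 10 higher and 6 lower, and with an estimated correlation none was, although 2 had an unadjusted p under 0.05. Fry called 11 lists, all higher, of which 9 were among the 16; the other 2 were the glutamate uptake and GABAergic lists (adjusted p = 0.0196 each), and none of the 6 lists called lower passed in it. Of 22 interferon response genes 17 rose, and of 19 complement and MHC genes 18 did (camera adjusted p = 5.6e-10 and 1.3e-09; adjusted p = 0.318 with an estimated correlation for each). Adjusted over the list alone the counts were 21 and 19. Oasl2 and Ifitm3 of the first list and C1qa, H2-K1 and H2-D1 of the second are induced in inflamed tissue, and H2 genes share reads with each other. Of 11 pan-reactive astrocyte genes 9 rose, including Cd44, and of 12 genes of the A1 reactive list 7 did, including Gbp2 and Iigp1; adjusted over the list alone the counts were 11 in each list. Their camera adjusted p were 5.4e-06 and 6.1e-05, and each had adjusted p = 0.318 with an estimated correlation. Several genes, H2-D1 among them, are members of both the A1 list and the complement and MHC list, so the counts of these lists are not independent. Of 7 genes of the A2 list 2 rose, Sphk1 and Cd109 (camera adjusted p = 0.0175; adjusted p = 0.433 with an estimated correlation); 6 rose adjusted over the list alone.

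Of 17 genes of disease-associated microglia 12 rose, among them Ctsz and Spp1 (camera adjusted p = 3.3e-06; adjusted p = 0.318 with an estimated correlation), and 15 adjusted over the list alone. Of 14 genes of homeostatic microglia 3 rose, Aif1, Olfml3 and Sall1, as many as adjusted over the list alone, and the list was not called (camera adjusted p = 0.668). General astrocyte markers were not called as a list (adjusted p = 0.988; adjusted p = 0.0070, higher, with a score of olfactory bulb markers as a covariate, but 0.436 with that score and an estimated correlation), with Aqp4 and Mlc1 the 2 of 23 that rose, and 1 adjusted over the list alone. Aqp4, the water channel of astrocyte endfeet, rose from 29.4 ± 1.64 to 49.0 ± 12.9 FPKM (SD, n = 5 each). Of 16 mural and meningeal genes 6 rose, among them Aldh1a2, Ogn and Fmod (camera adjusted p = 0.00298; adjusted p = 0.441 with an estimated correlation), and 9 adjusted over the list alone. The endothelial list was not called (adjusted p = 0.235), with Itm2a the 1 of 15 that rose and 0 adjusted over the list alone.

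Neuronal genes went both ways. Of 18 excitatory neuron layer genes 5 fell and 2 rose, and the list was called lower (camera adjusted p = 0.00224; adjusted p = 0.318 with an estimated correlation; adjusted p = 0.0561 with quantile normalization). Rasgrf2 and Cux2, markers of upper layers, had log2 fold changes of -0.61 and -0.69, and Rorb fell by 0.58. Of 23 immediate early genes 5 fell and 1 rose (camera adjusted p = 1.5e-05; adjusted p = 0.318 with an estimated correlation; adjusted p = 0.207 with the olfactory bulb score as a covariate), and Egr1 went from 78.1 ± 7.15 to 41.9 ± 16.4 FPKM (SD, n = 5 each), with Fosl2 and Nr4a3 also lower. Of 16 GABAergic interneuron genes 9 rose and 1 fell, with Gad1, Gad2 and Slc32a1, which make and load the transmitter GABA, higher by 0.57, 0.91 and 0.73 on the log2 scale. That list was not called (camera adjusted p = 0.171), but was with median-of-ratios scaling (adjusted p = 0.0324); without that scaling it had adjusted p = 0.658 with an estimated correlation. Of 14 striatal neuron genes 4 rose, among them Penk, Pdyn and Tac1 (camera adjusted p = 0.0116; adjusted p = 0.660 with an estimated correlation), and the list was not called without the library labelled KO3 (adjusted p = 0.0889). Adjusted over the list alone, 6 excitatory layer genes fell and 2 rose, 10 immediate early genes fell and 2 rose, 9 GABAergic genes rose and 2 fell, and 6 striatal genes rose. Markers of the olfactory bulb differed between libraries: Omp was between 2.95 and 10.5 FPKM in WT3, WT4 and KO1 to KO4, and between 0.23 and 0.41 FPKM in WT1, WT2, WT5 and KO5. Libraries with Omp of at least 1 FPKM were thus 2 of 5 in WT and 4 of 5 in KO, so these markers were partly confounded with genotype.

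Myelin genes were called lower as a list (camera adjusted p = 2.1e-07; adjusted p = 0.318 with an estimated correlation) although only Mal of 18 fell, and 7 did so adjusted over the list alone. Of 16 circadian clock genes 5 fell, Bhlhe40 and Cry2 among them, and 1, Bhlhe41, rose (camera adjusted p = 8.0e-06; adjusted p = 0.318 with an estimated correlation). None of 13 mitochondrially encoded genes and 1 of 11 glucocorticoid response genes, Zbtb16, fell. Those lists were called lower (camera adjusted p = 0.0300 and 0.0311; adjusted p = 0.667 and 0.617 with an estimated correlation), and neither was with median-of-ratios scaling (adjusted p = 0.117 for each) or with the olfactory bulb score (adjusted p = 0.180 and 0.905). Their means did not pass between KO and WT in the exact permutation test (p = 0.635 and 0.540). The glucocorticoid list was not called without the library labelled KO3 either (adjusted p = 0.0741). Of 28 genes of endoplasmic reticulum associated degradation, the process in which membralin takes part, 4 rose, among them Vcp, Derl1 and Erlin1 (camera adjusted p = 0.0116; adjusted p = 0.658 with an estimated correlation). Adjusted over the list alone, 6 clock genes fell and 1 rose, 4 degradation genes rose, and 0 mitochondrial and 0 glucocorticoid response genes passed. The unfolded protein response list was not called (adjusted p = 0.855), and Atf3 and Asns were the 2 of 23 that rose, also adjusted over the list alone. Lists of glutamate receptors (adjusted p = 0.143), oligodendrocyte precursors (0.0780), choroid plexus and ependyma (0.474), blood (0.171), cholesterol synthesis (0.580, and 0.00091, higher, with the olfactory bulb score, but 0.535 with that score and an estimated correlation), genes of human ALS (0.637), p53 and apoptosis (0.990) and the neighbours of Tmem259 (0.668) were not called by camera. Of the 22 receptor genes 2 rose and 2 fell, with Grin2a and Grm3 lower, and 4 rose and 2 fell adjusted over the list alone. Hnrnpa1 and Vcp rose among 19 ALS genes (7 rose and 2 fell adjusted over the list alone), and Cdkn1a and Bax among 13 p53 genes (4 rose and 1 fell). Foxj1 rose among 12 choroid and ependymal genes (0 adjusted over the list alone). No gene passed, over all genes or adjusted over the list alone, among the precursor, blood, cholesterol and neighbour lists. Among the members with the lowest p, Sox9, S100a10, Dnajb9, Mog, Mobp, Olig1, Olig2, Flt1, Cldn5, Aqp1, Ccdc153, Alas2, Hbb-bs, mt-Nd3, mt-Nd4l, mt-Atp8, Nsdhl, Sc5d, Chchd10, Sesn2, Mt2, Tsc22d3, R3hdm4, Cirbp and Sbno2 did not pass over all genes. The median, mean and camera direction differed in sign for the glutamate receptor, endothelial, choroid and neighbour lists.

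**Figure D2:**
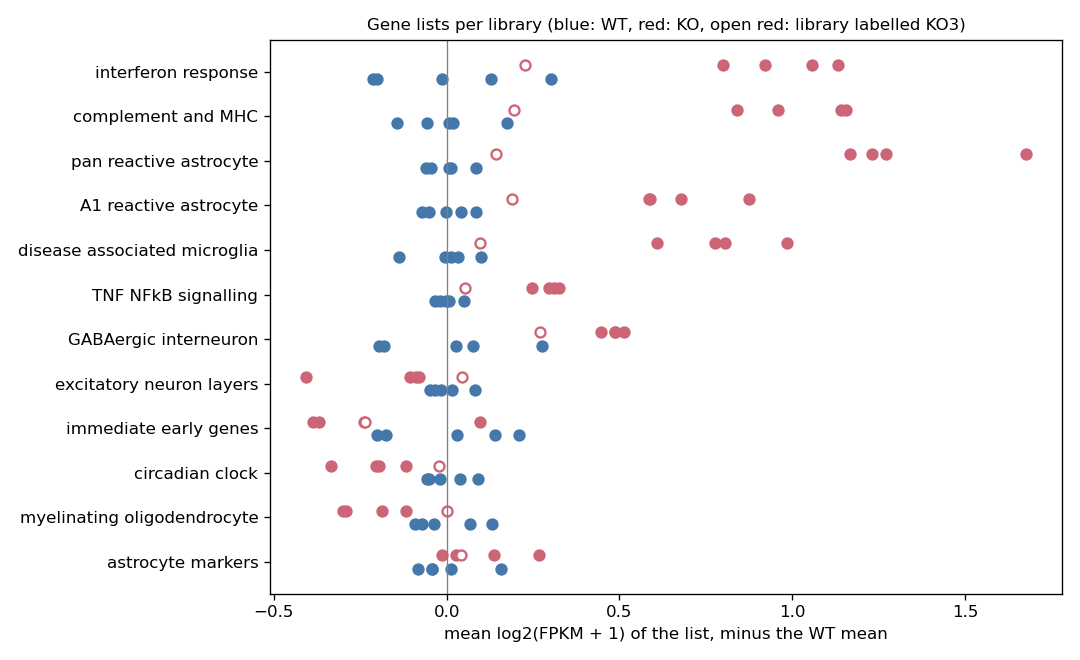
Mean log2(FPKM + 1) of 12 gene lists in each library, minus the WT mean of that list, with WT in blue, KO in red and the library labelled KO3 as an open circle. The complement and MHC list was 2.46 in the library labelled KO3 before subtraction, against 2.13 to 2.45 in WT and 3.11 to 3.43 in the other KO libraries.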

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

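All tests of explanations in this part were chosen after the results were seen, except those of the most abundant genes and of the splits for gene lists. Samples lay apart from the others of their group in 20 of 266 groups examined, where chance gives about 1 in 20, and 11 of the 20 were the library labelled KO3.

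That library was the highest KO value for Glul (817 FPKM), Rims1 (58.6 FPKM), Dgkz (135 FPKM) and Egr1 (70.5 FPKM). It was the lowest for Olfml3 (5.38 FPKM), Ctsz (27.1 FPKM) and Bhlhe41 (9.51 FPKM). It was also the lowest for the mean log2(FPKM + 1) of the A2 (1.53), tumour necrosis factor (1.92), GABAergic (4.35) and p53 (2.94) lists. Other samples apart from their group were WT5 for Cpne9 (9.96 FPKM), Mvk (11.6 FPKM), Bhlhe41 (9.31 FPKM) and the mitochondrial list (9.64), and WT4 for Nfkb2 (1.55 FPKM). Those in KO were KO2 for Sphk1 (2.37 FPKM) and Hba-a2 (10.8 FPKM), and KO5 for C1ql1 (12.8 FPKM) and Cdkn1a (34.7 FPKM).

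The library labelled KO3 was nearer to the WT mean for 80.8% of the 3763 genes called without it, against 5.92% to 21.4% for the other KO libraries by the same measure. An exchange of labels with a WT library is argued against, since no WT library was nearer to the KO mean for more than 18.0% of its genes. Low depth is argued against too, since KO5 had fewer fragments and was nearer to the WT mean for only 21.1%. A mouse or library without the knockout stays open: Tmem259 was 34.36 FPKM in it, but KO5 at 26.2 FPKM also lay above the lowest WT library, so that level does not separate such a library, and Prm1 was 0.55 FPKM in it and 22.9 to 49.0 FPKM in the other KO libraries, but also 12.8 and 44.5 FPKM in WT2 and WT3, so its lack does not settle the genotype. A wrong label, a sample from outside the series and a mouse with little recombination were not told apart by any test here.

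Of 16 GABAergic genes 9 were called higher and 1 lower in KO, in a list not called by camera (adjusted p = 0.171), and tissue of neighbouring regions is a candidate source for the 9. With the olfactory bulb score as a covariate the median log2 fold change of the 9 higher members was 0.73 (median SE 0.20), and 0.73 (median SE 0.18) without it, and that of all 16 was 0.30 with it and 0.56 without, while all 9 calls were lost, with a larger SE and 3417 rather than 4758 genes at an unadjusted p under 0.05, and 6 were kept when the library labelled KO3 was also left out. For the 44 genes called higher in the pan-reactive astrocyte, complement and MHC, and interferon lists the median was 0.79 with the score and 0.80 without, with 0 calls left, and 42 calls when the library labelled KO3 was also left out. Of 4 subcortical marker lists 0 had KO1, KO2, KO4 and KO5 each above every WT library, but the bound was missed by less than the WT SD in 3 of them and decides nothing. The hypothalamic (0.34 ± 0.073 in WT, 0.56 ± 0.22 in KO), thalamic (0.90 ± 0.037, 0.998 ± 0.071) and basal forebrain (0.97 ± 0.27, 1.42 ± 0.28) means (SD, n = 5 each) had exact permutation p of 0.0159, 0.0238 and 0.0317, 0.0529 each after adjustment over 5 lists, so such tissue stays open.

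More genes were called higher than lower (73.6% of 1926). With median-of-ratios scaling 41.0% were higher, but that scaling centres the median of all genes (0.0779 before, 0.0033 after), which fixes the balance, so scaling by the total stays open. With the gene length trend removed and the centre of each library kept 78.5% were higher. The loess correction, which also centres each library, gave 44.2%. Keeping the centre keeps any shift that the trend causes, and centring fixes the balance, so a gene length trend stays open. With the 100 most abundant genes left out of the totals 65.9% were higher, which lies between the bounds set beforehand and leaves open how much those genes contribute. Whether total RNA per cell differs between the genotypes was not tested.

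Among 100 of the possible splits of the 10 libraries, 1, the real one, gave as many genes as 1926, and the highest of the others gave 1122 genes, with the library labelled KO3 exchanged for WT2. A count as large was thus rare among the splits run, which argues against chance for the count of genes but does not exclude it. Exchanges of the library labelled KO3 for WT4 and for WT5 were not among those splits. A rank among splits also does not tell genotype from other differences between the groups. For gene lists 12 of the 100 splits gave 16 lists or more, with up to 19, so chance is not excluded for the count of called lists.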

How the results depend on the processing

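The limma-voom, olfactory bulb, gene length and further left-out fits were chosen after the data were seen. The number of genes called (1926) was 465 with no filter on low values, 3557 with arrayWeights, 3546 at an adjusted p under 0.10 and 370 with a fold of at least 1.5. It was 0 in the exact permutation test per gene (4363 at an unadjusted p under 0.05), whose smallest p is 0.00794, and 0 with limma and the olfactory bulb score (3417 at an unadjusted p) or in the 2 WT and 4 KO libraries with Omp of at least 1 FPKM (1908); limma-voom called 2128. Leaving out 1 library gave between 2 and 3763 genes, the lowest without WT1, KO2 or KO4 (3934, 4114 and 3742 at an unadjusted p). Replicate numbers did not meet the bound for pairing, every pair over 0.1 (correlations of deviations from -0.06 to 0.14, over 0.1 in 3 of 5 pairs, 4 of 10 samples closest to their own number), though numbers 1 to 3 lacked and 4 and 5 had Y-linked transcripts in both groups. A replicate block gave 1271 genes, 1140 of them shared, and ended 16 of the 70 calls of named genes. Tmem259 had log2 fold changes between -0.42 and -0.17 with 1 library left out, and passed only without the library labelled KO3. The 16 called lists became 9 at a mean of at least 5 FPKM, and 0 with an estimated correlation (2 at an unadjusted p) or in the exact permutation test of the list mean (16 at an unadjusted p). Of the 16 lists 13 were called in each of the 10 left-out fits. Without the library labelled KO3 (3763 genes), between 2415 and 3423 genes were called with a further library left out, and 2141 with the olfactory bulb score. Camera called 14 lists without that library, and 0 with an estimated correlation. The exact permutation test of the list mean called 16 lists without it, 12 of them among the 14. All 70 called named genes passed without the library labelled KO3, and 0 of them passed in every left-out fit; no called named gene changed the sign of its fold change and no called list its direction by camera, but with the olfactory bulb score the medians of the immediate early (-0.23 to 0.053) and glucocorticoid (-0.076 to 0.054) lists did. The majority of called genes turned from higher (1417 against 509) to lower with median-of-ratios scaling (625 against 901), quantile normalization (617 against 790), loess on gene length (568 against 716) and limma-voom with median-of-ratios sizes (711 against 1021). Of the 70 calls of named genes, median-of-ratios scaling ended 14 and quantile normalization 15. Causes were not tested beyond the sizes of the fits.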

Other observations

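Genes of this part were chosen after their values were seen. Wfs1, an endoplasmic reticulum membrane protein, was between 69.2 and 106 FPKM in KO1, KO2, KO4 and KO5, and between 28.9 and 39.2 FPKM in WT and the library labelled KO3 (38.7 FPKM). Lhx2 and Nr2f1, transcription factors of cortical patterning, were 14.9 to 16.5 and 15.8 to 17.2 FPKM in those KO libraries, against 21.7 to 27.7 and 21.2 to 26.2 FPKM in WT. Th, the rate-limiting enzyme of dopamine synthesis, was between 5.39 and 13.1 FPKM in KO and, in WT, 5.74 and 3.43 FPKM in WT3 and WT4, the WT libraries with Omp, and between 0.83 and 1.16 FPKM in the others. Gal, a neuropeptide, was 2.55, 1.05, 8.15 and 9.72 FPKM in KO1, KO2, KO4 and KO5, 0.24 FPKM in the library labelled KO3 and between 0 and 0.80 FPKM in WT. Slc6a5, a glycine transporter of glycinergic neurons, was 1.86, 0.37, 4.36 and 8.21 FPKM in KO1, KO2, KO4 and KO5, 0 in the library labelled KO3 and at most 0.049 FPKM in WT.

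Prm1, a gene of sperm chromatin, was 22.9, 47.7, 49.0 and 42.1 FPKM in KO1, KO2, KO4 and KO5, 0.55 FPKM in the library labelled KO3, 12.8 and 44.5 FPKM in WT2 and WT3, and at most 0.52 FPKM in WT1, WT4 and WT5. The pseudogene Tma7-ps was between 22.2 and 34.7 FPKM in WT1, WT2, WT3 and WT5, and at most 0.63 FPKM in WT4 and all KO libraries. Gm15487 was 5.93 to 9.47 FPKM in KO1, KO2 and KO4 and at least 103 FPKM in the other 7 libraries. The hindbrain marker list was 0.096 ± 0.0083 in WT and 0.084 ± 0.015 in KO (mean log2(FPKM + 1), SD, n = 5 each; exact permutation p = 0.183), and the olfactory bulb list 1.02 ± 0.77 and 2.18 ± 0.87 (p = 0.0476, 0.0595 after adjustment over the 5 lists).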
